A study of Mus musculus with 2 samples.

How the data were processed

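The series holds 2 Affymetrix MOE430 2.0 arrays, each hybridized with biotin-labelled cRNA from total RNA of mouse embryonic stem (ES) cells. 1 array carries the control cells and 1 the constitutive Eed knockout (Eed KO) cells. A probe set is a group of short oligonucleotides whose hybridization is summarised into 1 signal, and a gene can have several. Per the submitters' processing notes, the signals were computed with MAS5, with no version given there. MAS5 estimates a background-corrected signal for each probe set on each array separately. The deposited values are probe set intensities on a linear scale. They were already scaled when deposited: the mean after dropping the lowest and highest 2% of the 45101 probe sets was 500.00 on both arrays. The deposited table used here holds 1 intensity per probe set and array, with no detection call and no standard error. No genome build enters these values.

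The groups were taken from the sample titles. With 1 array in each group there is no replicate, so no SD, standard error or p-value was computed, and every difference is a difference between these 2 arrays. The number of arrays limits the precision of every value below.

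Probe sets were named from the platform annotation: 34945 had 1 gene symbol, 932 had several and were not named, 9160 had none in that table, and 64 were the manufacturer's control probe sets (names starting with AFFX). Of the probe sets with 1 symbol, 34741 had a gene ID in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and gave each gene's chromosome. The 34945 probe sets stood for 18193 genes, and each gene was represented by its probe set with the highest mean log2 signal over both arrays. A floor of 61.3 was set at the 40th percentile of all non-control signals of both arrays together. Signals under the floor were set to it before ratios were taken, so that a ratio against such a value is a lower bound and is written as "at least". The control probe sets for the tryptophan gene Trpn, which matches no mouse transcript, reached at most 23.2. A gene counted as measured when it was above the floor on at least 1 array, which held for 13794 genes. A gene was called higher or lower when its floored signals differed by at least 2-fold.

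26 gene lists, the rule for the genes named in the text, the floor and the 2-fold size were fixed before the data were examined. The rule named Eed, a short set of Polycomb, pluripotency and lineage genes, the 10 genes with the largest ratio in each direction among those above the floor on both arrays, the 8 with the largest lower bound in each direction, and up to 4 of the most different members of each list. Clone-style names were counted but not printed. The gene T, which the rule also named, is not analysed here. List names were matched to symbols, or to a unique synonym. The median log2 ratio of a list's measured genes was set against the medians of 10000 random lists of the same size drawn from the measured genes within 20 bins of mean log2 signal. The resulting percentile describes these 2 arrays and is not a p-value. It was computed for 24 lists with at least 5 measured genes. Chromosomes were treated in the same way over genes above the floor on both arrays.

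The only repeated measurement within an array pair is that by different probe sets of a gene. The SD of a probe set's log2 ratio, taken as the SD of the difference between the best and the next probe set of a gene divided by the square root of 2, was 0.54 at signals up to 128, 0.33 between 256 and 512 and 0.18 above 2048. It covers technical and isoform spread only. The procedure was tested on simulated data: on a simulated array pair of 18193 genes with that spread, 200 genes were changed. Of the 25 genes raised 3-fold 25 were called, and of the 25 lowered 3-fold 23. At a true change of 2-fold 15 of 25 raised and 10 of 25 lowered genes were called. At 8-fold 25 of 25 raised and 19 of 25 lowered genes were called, since lowered genes run into the floor. Among 13051 unchanged genes 117 were called higher and 42 lower. The simulated pair had no difference in scale, no intensity trend and no variation between samples. These counts therefore do not give the rate of false calls in the real pair. Of 100 lists of 20 genes drawn at random from all measured simulated genes, changed ones included, 3 fell outside the middle 95% of random lists. As these were themselves random lists, the limit sets about how many fall outside. This checks the computation only, and not how lists of related genes behave.

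Alternatives planned before the data were examined were quantile normalization, scaling to the same median, removal of an intensity-dependent lowess trend (span 0.3), scaling on the bacterial hybridization spikes, floors at the 25th and 60th percentile, a pseudocount in place of the floor, the mean over a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, and calls at 1.5-fold and 3-fold. Scaling on the poly-A spikes was added after seeing the data. Runs of these alternatives for most genes and the 2 lists named later, and for the direction of every called gene, were also added then. List medians were compared across alternatives as the excess over the median of the random lists, a form chosen after seeing the data because a change of scale shifts every list. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.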

Results

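Gene expression was measured in mouse ES cells labelled as Eed knockout (Eed KO) and in cells labelled as control, with 1 microarray each. Eed is a core subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3 at silent developmental genes. The comparison asks which transcripts differ between the 2. The submitters set it beside knockouts of the PRC1 proteins Ring1A and Ring1B, which are not analysed here. The labels do not say how the gene was disrupted, whether the 2 lines share a parent line, or whether the cells were grown on feeder cells. As there was 1 array per group, none of the differences below has a replicate check and no test between conditions could be made.

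In the Eed KO array, 15 of 25 germline genes, 20 of 25 fibroblast markers, 7 of 17 trophectoderm markers, 10 of 26 endoderm markers and 3 of 8 inhibitors of cyclin-dependent kinases were at least 2-fold higher than in the control array, and 2 endoderm markers were at least 2-fold lower. All 21 Hox genes had a ratio above 1, at low signal, and 4 reached 2-fold. For 13 of the 21 that direction was fixed in advance, as they were under the floor in the control and measured only in the Eed KO. The core pluripotency genes Pou5f1, Sox2 and Nanog stayed within 2-fold. Of 13 primed epiblast markers, 5 were at least 2-fold lower and 2 higher. The lower ones included Dnmt3a (11.2-fold, log2 ratio -2.00 as the mean over probe sets) and Pou3f1 (6.77-fold). In all, 1483 genes were at least 2-fold higher and 451 at least 2-fold lower with the deposited scaling. With the arrays scaled to the same median 873 were higher and 1034 lower. A larger share of fibroblasts in the Eed KO sample was not excluded as a source of the higher lists.

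The signals spanned a similar range on both arrays. The median over all 45101 probe sets was 87.4 in the control and 108.1 in the Eed KO, the 90th percentile was 1684 and 1641, and the highest signal was 45140.1 and 50244. The 18 probe sets for the bacterial hybridization spikes had a median Eed KO over control ratio of 1.05 and a highest ratio of 1.22. The 24 probe sets for the poly-A spikes, which enter before labelling, had a median ratio of 1.15. The ratio of 3′ to 5′ signal, a measure of RNA integrity, was 0.791 in the control and 0.789 in the Eed KO for Gapdh, and 1.26 and 1.28 for Actb.

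The Eed transcript itself was not clearly lower in the Eed KO. Its main probe set read 10101 in the control and 11456 in the Eed KO, a 1.13-fold ratio, and its other probe set was under the floor on both arrays at 49.0 and 56.7. The log2 ratio of 0.18 went as low as -0.13 under other scalings, with the sign turned in 2 of them. Since the labels do not place the disruption in the gene, a probe set outside the disrupted part checks nothing, and this signal neither bears out nor contradicts the label. Among the other PRC2 genes, Ezh2, the methyltransferase, read 4551 and 4244 (log2 ratio -0.10, turning to 0.01 in 1 alternative), and Suz12 read 3757 and 6566 (1.75-fold higher). All 5 further Suz12 probe sets were higher too, by 0.88 to 2.24 on the log2 scale. Of the 12 PRC2 genes measured, 0 differed by 2-fold, although 1 was higher as the mean over probe sets (Suz12, log2 ratio 1.19) and 1 lower without probe sets shared with other transcripts. Of the 20 PRC1 genes measured, 2 were at least 2-fold higher and 0 lower, or 1 and 2 with the arrays scaled to the same median. The 2 higher were Bmi1, a Polycomb ring finger protein (279.0 to 1197, 4.29-fold), and Cbx8, a chromodomain protein (70.1 to 140.2, exactly at 2-fold and under it in 6 alternatives). Rnf2, which encodes Ring1B, had a log2 ratio of 0.09, with the sign turned in 3 alternatives, and Ring1 had one of -0.11. The medians of both lists lay within the middle 95% of random lists, as did that of the H3K27 demethylases and trithorax methyltransferases, where 1 of 12 genes was higher (the Y-linked Uty, under 2-fold in 2 alternatives).

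Across the genome, 1483 of the 13794 measured genes (10.8%) were at least 2-fold higher in the Eed KO and 451 (3.3%) at least 2-fold lower. Above the floor in the Eed KO only were 1497 genes, and in the control only 482, so their direction was fixed by the floor. They gave 315 of the higher calls and 50 of the lower ones. The floor of 61.3 lay above the control's 40th percentile (54.7) and below that of the Eed KO (68.8). The excess of higher genes lay mostly at low signal: among the 8013 genes with a mean signal under 10 times the floor 1188 were higher and 247 lower, and among the 5781 brighter genes 295 were higher and 204 lower. Higher genes made up 76.7% of the calls with the deposited scaling. They made up 64.6% after quantile normalization, 66.2% after removal of the intensity trend, 70.4% with scaling on the hybridization spikes, 57.6% with scaling on the poly-A spikes and 45.8% when the arrays were scaled to the same median, which moved the median log2 ratio of all measured genes from 0.12 to -0.16. The poly-A scaling moved that median to -0.06, so list medians below are set against random lists of the same arrays. Where a called gene had a second measured probe set, that probe set went the same way for 623 of 659 higher genes (94.5%) and 188 of 210 lower genes (89.5%), and by at least 1.5-fold for 491 and 147 of them.

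**Figure D1:**
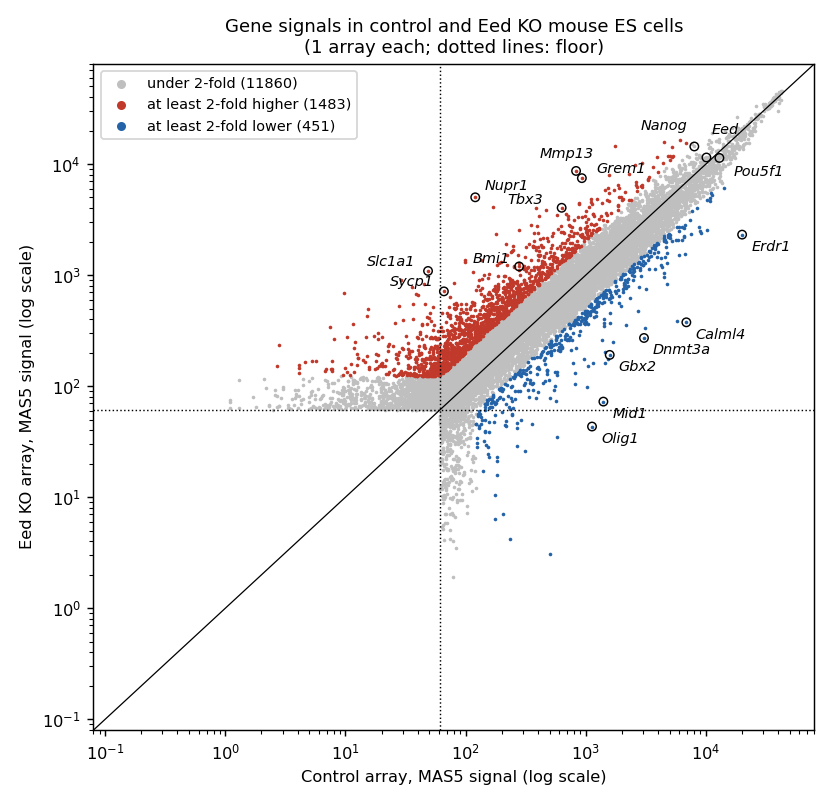
Signal of each measured gene in the control array (x axis) and the Eed KO array (y axis), both on log scales, with 1 point per gene. The 1483 genes at least 2-fold higher and the 451 at least 2-fold lower in the Eed KO are coloured, dotted lines mark the floor of 61.3, and Eed lies next to the line of equal signal.

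The gene with the largest ratio measured on both arrays was Nupr1, a stress-induced transcriptional regulator, at 120.3 in the control and 5017 in the Eed KO (41.7-fold). Chac1, a glutathione-degrading enzyme, followed at 24.4-fold (168.3 to 4099). The secreted matrix proteases Mmp3 (13.1-fold) and Mmp13 (10.4-fold, 830.5 to 8668), the pentraxin Ptx3 (13.9-fold), lipoprotein lipase Lpl (13.3-fold), the meiotic synaptonemal complex gene Sycp1 (10.8-fold) and the transcription factor gene Jdp2 (10.1-fold) were among the first 10. Fibroblast markers were higher in the same array, by a median log2 ratio of 1.49, and which cells gave these largest ratios was not tested. At the lowest among the alternatives, Ptx3 and Jdp2 had log2 ratios of 1.61 and 1.80 (as means over probe sets), and Lpl and Sycp1 of 2.95 and 2.09 (with the floor at the 60th percentile). The first 10 also held Vldlr (10.7-fold) and Zfp934 (10.5-fold). The 4 other measured Vldlr probe sets had log2 ratios of 0.10 to 2.66, and the gene fell to 0.10 when probe sets shared with other transcripts were left out, while the other Zfp934 probe set had a log2 ratio of 0.17 (1.78 as the mean). Among genes under the floor in the control, the glutamate transporter gene Slc1a1 was at least 17.8-fold higher (1090 in the Eed KO), Stk25 at least 14.7-fold, Atp12a at least 13.7-fold, Sirt2 at least 12.9-fold, Pramel18 at least 11.2-fold, Bhmt at least 11.1-fold and arginase 2 (Arg2) at least 10.9-fold. These bounds are set by the floor, and with the floor at the 60th percentile the log2 ratios were between 2.70 (Slc1a1, from 4.15) and 1.99 (Arg2, from 3.45). Pag1 (at least 8.90-fold) had another probe set going the other way, and its log2 ratio was 0.55 as the mean over probe sets.

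In the other direction, Calml4 was 18.3-fold lower (6872 to 375.8), the de novo DNA methyltransferase gene Dnmt3a 11.2-fold (3052 to 271.6, with 4 further measured probe sets at log2 ratios of -3.26 to -0.49 and a mean over probe sets of -2.00), Dpys 10.3-fold, Trh, encoding thyrotropin-releasing hormone, 9.45-fold, the neurofilament gene Ina by a log2 ratio of -3.17, the peptide hormone gene Apela 8.81-fold and the homeobox gene Gbx2 8.28-fold (1583 to 191.2). Mid1 (19.3-fold), Rpgrip1 (14.7-fold) and Erdr1 (8.64-fold, 20005 to 2315) were also in this group. Mid1 and Rpgrip1 had log2 ratios of -0.96 and -0.72 as means over probe sets, and Erdr1 of -0.82 without probe sets shared with other transcripts. The other measured Mid1 probe set went the other way (0.44). The oligodendrocyte lineage factors Olig1 (1127 to under the floor, at least 18.4-fold) and Olig2 (499.9 to under the floor, at least 8.15-fold) had large lower bounds, as had Tmem267 (at least 9.42-fold). With the floor at the 60th percentile the log2 ratios of Olig1, Olig2, Tmem267 and Dpys were -2.74, -1.57, -1.78 and -2.59. Trim34a, Nkx6-3, Insm1, Thbs3 and Plvap were at least 4.35- to 5.05-fold lower, and each was under 2-fold with the floor at the 60th percentile.

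The core pluripotency factors had high signals on both arrays. Pou5f1, which encodes Oct4, read 12948 in the control and 11352 in the Eed KO (1.14-fold lower), Sox2 11826 and 8531 (1.39-fold lower) and Nanog 8007 and 14393 (1.80-fold higher). Of the 30 pluripotency genes measured, 5 were at least 2-fold higher, 2 lower and 23 within 2-fold. The higher ones were Tbx3 (630.1 to 4038, 6.41-fold), Prdm14 (4.67-fold), Jam2 (3.92-fold), Klf4 (2.59-fold) and Tcl1 (1473 to 3633), and the lower ones Dppa4 (7304 to 3129) and Gdf3 (3821 to 1869). Tcl1, Dppa4 and Gdf3 were named after their values were seen. Gdf3 was under 2-fold after quantile normalization, after removal of the intensity trend and as the mean over probe sets (log2 ratio up to -0.82), and Tcl1 (0.99) with the arrays scaled to the same median, where 4 genes of the list were higher and 5 lower. The list's median log2 ratio of 0.02 lay within the middle 95% of random lists.

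Among 13 measured markers of the primed, post-implantation epiblast, 6 had a ratio above 1 and 7 below, with 5 at least 2-fold lower and 2 higher. The list's median of -0.39 lay at percentile 0.6 of random lists, whose middle 95% spanned -0.29 to 0.44. Besides Dnmt3a, the lower ones were the POU factor gene Pou3f1 (1678 to 247.9, 6.77-fold), and Lef1, Dnmt3b and Otx2, with log2 ratios of -1.48, -1.12 and -1.03, which were named after their values were seen. Lef1 (-0.94 with the floor at the 60th percentile and -0.90 as the mean over probe sets) and Otx2 (-0.97 with a pseudocount) fell under 2-fold. The higher ones were the Nodal antagonist Lefty2 (4.04-fold) and follistatin, Fst (3.54-fold).

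Genes of the Hox clusters were higher as a group, at low signal. All 21 measured Hox genes had a ratio above 1, although 1 fell below it after quantile normalization and after removal of the intensity trend. The list had a median log2 ratio of 0.76 at percentile 100 (rounded) of random lists, and 4 genes reached 2-fold. The 4 were Hoxd13 (61.6 to 316.4, 5.14-fold), Hoxd8 (79.6 to 285.6, 3.59-fold), Hoxa11 (84.3 to 220.6, 2.62-fold) and Hoxb2 (under the floor to 149.0, at least 2.43-fold). Fibroblast markers were higher in the same array, by a median log2 ratio of 1.49, and shared 0 genes with this list. A count of shared genes cannot tell a list's change apart from a larger share of fibroblasts, here or for any list below. Of the 21 genes, 13 were under the floor in the control and counted as measured only through the Eed KO. A ratio above 1 was therefore fixed in advance for these 13. The count at 2-fold depended on the floor. With it at the 25th percentile, 15 of 29 Hox genes were at least 2-fold higher and 2 had a ratio below 1, and with a pseudocount 7 of 21 were higher. With the floor at the 60th percentile only 6 Hox genes were measured, the excess over random lists was 0.03 rather than 0.41, at percentile 56.7, and Hoxd13, Hoxd8 and Hoxa11 had log2 ratios of 0.91, 0.76 and 0.39.

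Other developmental regulators went in both directions. Of 50 measured homeobox and paired-box genes outside the Hox clusters, 14 were at least 2-fold higher and 1 lower, and 10 of 51 were higher and 3 lower with the arrays scaled to the same median. Of the 50, 26 were above the floor on 1 array only, which fixed their direction. The higher ones included the mesenchymal factor Prrx1 (136.1 to 931.4, 6.84-fold), Meis2 (at least 6.80-fold) and Vax2 (5.55-fold), and the lower one was Gbx2. At their lowest among the alternatives Prrx1, Meis2 and Vax2 had log2 ratios of 1.84, 1.31 and 1.17. The list's median of 0.50 lay at percentile 96.5, inside the middle 95%. Alternatives ranged from 75.7, with the floor at the 25th percentile, to 99.9, with a pseudocount. It was outside the middle 95% with the pseudocount and as the mean over probe sets. Prrx1 is the 1 member that is also on the fibroblast list, whose median was 1.49. Of 54 measured T-box, Gata, Fox, Sox and basic helix-loop-helix genes, 17 were higher and 7 lower, and the median of 0.33 lay at percentile 54.1. Again 17 of the 54 were above the floor on 1 array only. Snai2 was 6.60-fold higher, with a log2 ratio of 0.20 when its shared probe set was left out, and the lower genes included Olig1, Olig2 and the proneural factor Neurod1 (813.5 to 104.5, 7.78-fold, and a log2 ratio of -2.27 with the floor at the 60th percentile). After removal of the intensity trend the count of higher genes in this list was 11.

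Of 26 endoderm markers, 10 were at least 2-fold higher and 2 lower (median 0.80, percentile 100, rounded). Sox17 was 4.02-fold higher (120.3 to 483.2, but a log2 ratio of 1.10 for its other probe set), Sox7 3.87-fold (log2 ratio 0.97 with the floor at the 60th percentile), Gata6 2.80-fold (121.8 to 341.1) and the thrombomodulin gene Thbd 5.61-fold (270.4 to 1518), while Spink1 was 4.34-fold lower. Gata4 was 2.22-fold higher (103.5 to 229.8) but under 2-fold in 7 alternatives, down to a log2 ratio of 0.45. Gata4, Gata6, Sox7 and Sox17 are also on the T-box, Gata, Fox, Sox and basic helix-loop-helix list, so the lists are not independent. Of 17 trophectoderm and placenta markers, 7 were higher and 0 lower, or 4 and 1 with the arrays scaled to the same median (median 0.99 as deposited, percentile 100, rounded). Hand1 was 4.48-fold higher (156.6 to 702.2), Esx1 3.80-fold, the keratin gene Krt19 3.56-fold and Plac1 2.84-fold (0.82 on the log2 scale with the floor at the 60th percentile). The keratin genes Krt7, Krt8, Krt18 and Krt19 are on both this list and the epithelial list below. Fibroblast markers were higher in the same array, by a median log2 ratio of 1.49. They shared 0 genes with the endoderm or trophectoderm list, but that count cannot tell these changes apart from a larger share of fibroblasts. Cdx2, the factor that specifies trophectoderm, was under the floor on both arrays at 43.0 and 47.8. Of 20 primitive streak and mesoderm markers, 4 were higher and 1 lower (median 0.28, percentile 36.1), among them Gata2 (2.91-fold) and Eomes (2.49-fold, but 0.89 on the log2 scale with the floor at the 60th percentile). The lower one, Foxf1, had a second probe set going the other way, and a log2 ratio of -0.12 as the mean over probe sets. Of 24 neural markers, 2 were higher and 3 lower, against 1 and 5 of 25 after quantile normalization and after removal of the intensity trend and 1 and 6 of 25 with the arrays scaled to the same median, and the median of -0.19 lay at percentile 0.1. Of the 24, 7 were above the floor on 1 array only. The 3 lower genes, Olig2, Neurod1 and Sox11, are also on the T-box, Gata, Fox, Sox and basic helix-loop-helix list. Sox11 was 6.11-fold lower (806.1 to 132.0, with 5 further probe sets lower), and the retinoic acid binding protein gene Crabp1 was 4.30-fold higher. Pax6 was 1.47-fold lower at a signal of 94.9 in the control. When the mean over probe sets was used, the neural list's percentile was 14.7, and with the floor at the 60th percentile it was 4.9, both inside the middle 95%.

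Genes of the germ line were higher in the Eed KO as a group. Of 25 measured, 15 were at least 2-fold higher and 0 lower (median 1.42, or 2.68-fold, percentile 100, rounded). Besides Sycp1 they included Mael, a piRNA pathway gene (370.6 to 2394, 6.46-fold), the meiotic cohesin gene Smc1b (under the floor to 363.9, at least 5.94-fold, and a log2 ratio of 1.11 with the floor at the 60th percentile) and Dazl, an RNA-binding regulator of germ cells (137.8 to 773.0, 5.61-fold). The list's excess over random lists was 0.99 or more under all alternatives run. Of the 25 genes, 6 were above the floor on 1 array only, which fixed their direction. Fibroblast markers, higher by a median of 1.49 in the same array, shared 0 genes with it.

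**Figure D2:**
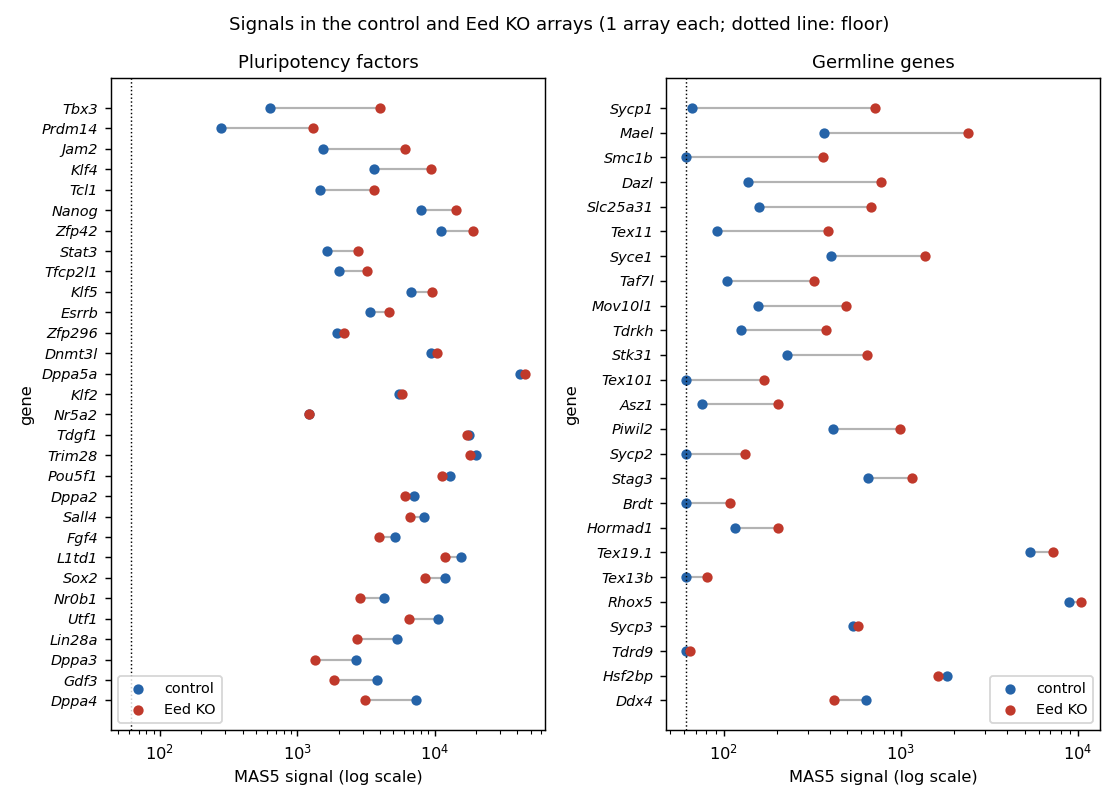
MAS5 signal (x axis, log scale) of each measured pluripotency gene (left) and germline gene (right) in the control array (blue) and the Eed KO array (red), ordered by ratio, with signals under the floor drawn at the floor. Tbx3 is at the top of the pluripotency genes with 6.41-fold, and 15 of the 25 germline genes are at least 2-fold higher.

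Markers of fibroblasts, a cell type that ES cell cultures can contain as feeder cells, were higher throughout. Of 25 measured, 20 were at least 2-fold higher and 0 lower, and the median log2 ratio was 1.49 (2.81-fold, percentile 100, rounded). Prrx1 was 6.84-fold higher, the chemokine gene Ccl2 4.44-fold (1097 to 4872), and the collagen gene Col6a1 3.69-fold (81.3 to 300.0, log2 ratio 0.83 with the floor at the 60th percentile). Decorin, Dcn, was 4.76-fold higher (116.3 to 554.1), but at a log2 ratio of only 0.02 as the mean over its probe sets, of which the other was under the floor on both arrays. All 25 were above the floor in the control too, and all 25 had a ratio above 1 under the 5 other scalings. Haematopoietic and endothelial markers did not move with them (1 of 12 higher, Flt1 at 3.32-fold but a log2 ratio of 1.04 with the floor at the 60th percentile, median 0.39, percentile 64.5), nor did epithelial markers (4 of 16 higher, 2 lower, or 1 and 2 with the arrays scaled to the same median, median 0.21, percentile 88.7), where Krt8 was 2.13-fold higher (under 2-fold in 2 alternatives), Dsp had a log2 ratio of 1.07 (under 2-fold in 7 alternatives, down to 0.46) and the epithelial regulator Grhl2 2.81-fold lower.

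Among signalling ligands and antagonists 9 of 32 genes were at least 2-fold higher and 2 lower (median 0.53, percentile 99.4, and 96.3 as the mean over probe sets, inside the middle 95% of random lists). The BMP antagonist gremlin, Grem1, was 8.04-fold higher (928.1 to 7465), Wnt4 6.12-fold (log2 ratio 1.26 as the mean over probe sets) and Wnt11 3.47-fold (log2 ratio 0.92 with the floor at the 60th percentile), and Fgf17 was 4.40-fold lower. Of the 32 genes, 9 were above the floor on 1 array only, which fixed their direction. The fibroblast markers' median of 1.49 stands beside this list too, with 0 shared genes. In the same array, and again with 0 genes shared with the fibroblast list, all 8 inhibitors of cyclin-dependent kinases had a ratio above 1 (median 0.99, percentile 99.7) and 3 reached 2-fold: Cdkn2a, which encodes p16 and p19Arf and is a known Polycomb target (under the floor to 174.2, at least 2.84-fold), Cdkn2b (326.8 to 795.7, 2.43-fold, and 0.98 on the log2 scale with the arrays scaled to the same median) and Cdkn2c (2.21-fold, under 2-fold in 5 alternatives). Cdkn2a was near the floor, and its log2 ratio was 0.05 with the floor at the 60th percentile. Cell cycle genes were slightly lower (median -0.33, percentile 0.7) with 1 of 24 at least 2-fold higher, Ccnd2 (2.57-fold), and 1 lower, Ccne1 (2.38-fold).

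**Figure D3:**
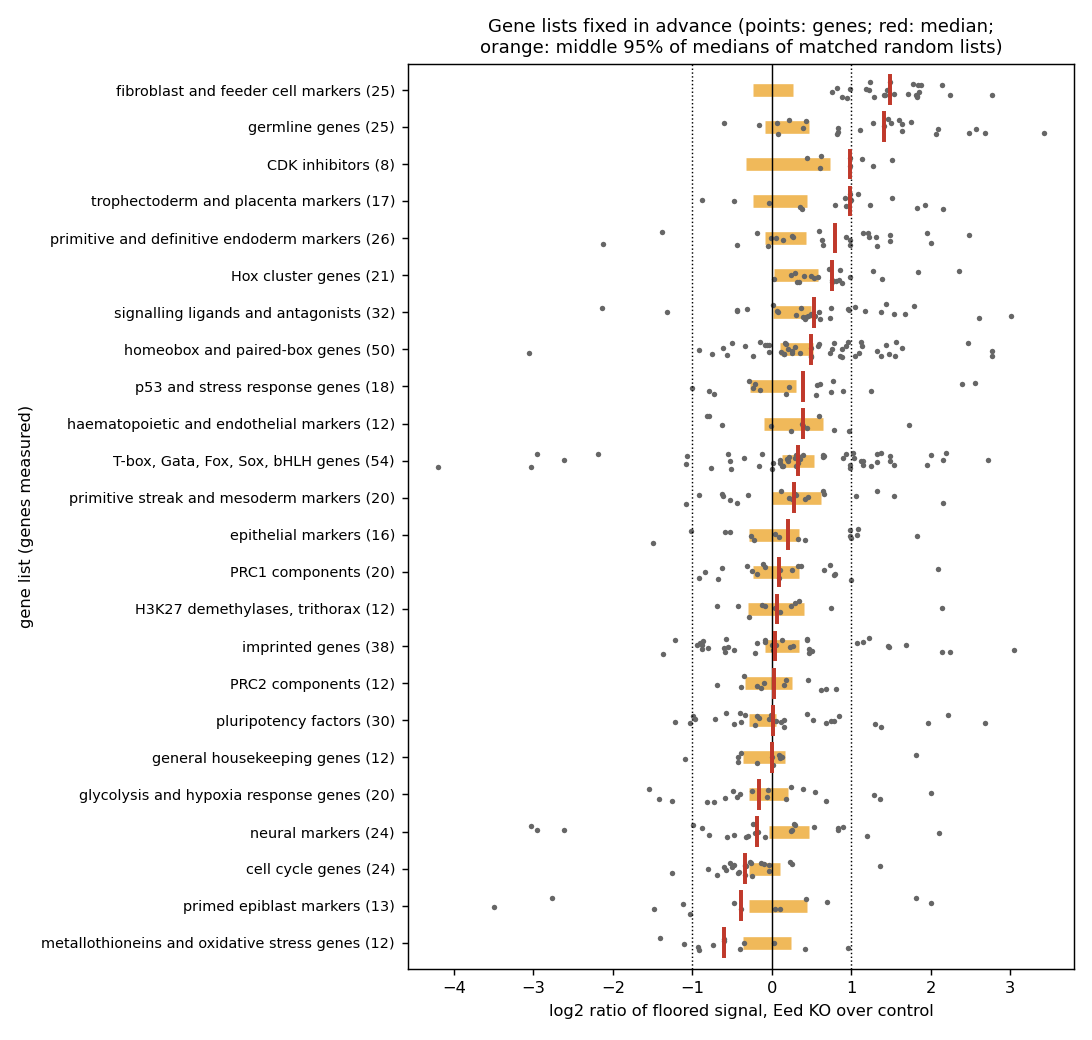
log2 ratio of Eed KO over control signal (x axis) for the measured genes of each gene list (points), with the list's median in red and the middle 95% of the medians of 10000 matched random lists in orange. Dotted lines mark 2-fold, and the fibroblast (median 1.49) and germline (1.42) lists lie farthest above their random lists.

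Imprinted genes, some of which are controlled through Eed, showed no common direction: 9 of 38 were at least 2-fold higher and 2 lower (median 0.04, percentile 23.2). This split depended on the scaling, with 7 higher and 6 lower after quantile normalization, after removal of the intensity trend and with scaling on the poly-A spikes, and 6 higher and 8 lower with the arrays scaled to the same median. Dcn, 1 of the 9 higher genes, is also on the fibroblast list. Plagl1 was 8.26-fold higher (469.1 to 3874), but at a log2 ratio of 0.48 when probe sets shared with other transcripts were left out. Igf2 was 4.40-fold higher (627.5 to 2760) and Igf2r 3.22-fold. Xist, the RNA that silences an X chromosome, read 550.4 and 999.0 (1.82-fold higher, but past 2-fold without probe sets shared with other transcripts, at a log2 ratio of 1.35, and as the mean over probe sets, at 1.37), and Rlim, its X-linked activator, was 2.05-fold lower (under 2-fold in 2 alternatives). Of 4 measured Y-linked genes, Eif2s3y was 6.85-fold higher (181.4 to 1243) and Uty at least 4.43-fold (under the floor to 271.4, but a log2 ratio of 0.63 as the mean over probe sets). Uba1y, a Y-linked gene not on the list, was higher by both its probe sets (49.8 to 413.0 and 69.7 to 290.4). Sry and Kdm5d were within 2-fold at signals of at most 134.2, with their other probe sets under the floor. Signals this low do not speak against a difference in Y-linked genes.

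Among stress and p53 response genes 3 of 18 were at least 2-fold higher and 0 lower (median 0.39, percentile 99.3, and 95.5 as the mean over probe sets, inside the middle 95% of random lists), and 2 higher and 3 lower with the arrays scaled to the same median. This list shared 0 genes with the fibroblast markers, whose median in the same array was 1.49. The 3 higher ones were the stress transcription factors Atf3 (71.7 to 423.9, 5.91-fold, and a log2 ratio of 1.33 with the floor at the 60th percentile), Ddit3 (187.7 to 985.8, 5.25-fold) and Jun (2.38-fold, but 0.94 on the log2 scale with the arrays scaled to the same median). Genes of metal and oxidant defence were lower (median -0.60, percentile 0.0, with 2 of 12 at least 2-fold lower and 0 higher, or 5 and 0 with the arrays scaled to the same median), led by Gclm (3883 to 1457, 2.66-fold, and a log2 ratio of -0.89 as the mean over probe sets) and Gstm2 (2.16-fold). Glycolysis and hypoxia genes were split, with 3 of 20 higher and 3 lower, or 2 and 5 with the arrays scaled to the same median (median -0.16, percentile 15.9, and 1.7 with the floor at the 60th percentile). Vegfa was 4.03-fold and Pfkp 2.56-fold higher, and Pdk1 was 2.91-fold and Egln3 2.68-fold lower. Of 12 general housekeeping genes 10 were within 2-fold. The exceptions were B2m (1853 to 6522, 3.52-fold higher) and the transferrin receptor gene Tfrc (8485 to 3989.5, 2.13-fold lower). Tfrc was under 2-fold in 2 alternatives, but its other probe sets had log2 ratios of -1.50 and -1.62. This list's median log2 ratio of 0.01 and mean of -0.02 differ in sign.

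By chromosome, the 988 genes of chromosome 11 had a median log2 ratio of 0.24, against 0.07 in matched random lists (percentile 100, rounded). Those of chromosomes 1 and 6 had medians of 0.18 and 0.19 against 0.09, at percentile 99.9 each. Chromosomes 7 and 8 had medians of -0.01 and -0.03 against 0.11 and 0.07 (percentile 0.0 each). Chromosomes 15 and 19 also lay below random lists, by a log2 difference of -0.08 and -0.07 (percentiles 0.6 and 2.2), but inside the middle 95% under some alternatives (percentiles up to 5.6 and 3.2). The X chromosome, with a median of 0.10, lay at percentile 64.9. The direction of chromosomes 1, 6, 7, 8 and 11 relative to random lists was kept under all alternatives run. Whether the 2 lines differ in chromosome number was not tested, and such a difference cannot be told apart here from the loss of Eed.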

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

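The tests of the fibroblast markers, of the Eed signal and of the excess of higher genes were chosen after the results were seen, and the limits of the tests on the share of higher genes were set with the share after removal of the intensity trend already known.

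Probe sets with no gene name in the annotation used here took no part in the comparisons, yet 215 of the 3984 above the floor on at least 1 array were at least 2-fold higher in the Eed KO, and 151 were at least 2-fold lower. Among those above the floor on both arrays, the most raised went from 119.9 to 7619 (63.5-fold) and the next from 94.2 to 1694 (18.0-fold), while the most lowered went from 2547 to 296.3 and the next from 3004 to 475.3. No explanation was tested for these.

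Fibroblast markers were higher in the Eed KO by a median log2 ratio of 1.49, including the abundant transcripts Ccn2 (4521 to 15919), S100a6 (5185 to 14139) and Vim (4989 to 11776, and a log2 ratio of 0.93 with the arrays scaled to the same median). After removal of the intensity trend between the arrays, all 25 markers still had a ratio above 1, and their median log2 ratio was 1.56. This argues against that trend as the source of the higher markers. The list then lay 1.55 above random lists, at percentile 100 (rounded), against 1.48 with the deposited scaling. That excess cannot test the trend, because the random lists were already matched on mean signal. A larger share of feeder fibroblasts may account for the shift, as all 25 markers were higher, but their log2 ratios had an SD of 0.49 against a measurement SD of 0.26, and ES cells may express these genes at levels of their own. Whether feeder cells were present is not given in the sources used here. Higher expression in the Eed KO cells themselves stays open and could not be told apart from it with 1 array per group.

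The Eed signal was not clearly lower in the Eed KO, at a log2 ratio of 0.18. It may come from a transcript kept with the probe set outside the altered part of the gene, which these values cannot decide because the position of the alteration is not in the labels. Exchanged labels would need the developmental regulator lists to be lower than random lists in the array labelled Eed KO. After removal of the intensity trend the Hox list lay 0.40 above them, at percentile 99.6, but the homeobox list lay at 94.8 and the T-box, Gata, Fox, Sox and basic helix-loop-helix list at 59.7, and fibroblast markers were higher in the same array, so an exchange was not excluded. Directions throughout therefore rest on the labels.

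More genes were higher than lower in the Eed KO, with 76.7% of calls higher. Removing an intensity trend left 1109 higher and 566 lower calls, or 66.2% higher, so the trend may account for part of the excess, and as the whole cause it is neither borne out nor excluded. A first limit of 60%, which this share passed and which would have excluded the trend, was replaced afterwards because it had been set with the share known and the share has no spread here. An overall scale set too high for the Eed KO array stays open. The share was 57.6% with scaling on the poly-A spikes and 45.8% with the arrays scaled to the same median, but 70.4% with scaling on the hybridization spikes. A loss of PRC2 repression could give such an excess too, and these cannot be told apart here.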

How the results depend on the processing

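Scaling on the poly-A spikes was chosen after seeing the data, as was the use of excess over random lists. No list past its limit and none of the 105 named genes at least 2-fold different changed direction, but 22 of all 1934 called genes did in at least 1 alternative, 16 of them as the mean over probe sets and 6 without shared probe sets, while Eed, Ezh2 and Rnf2, all within 2-fold, turned sign in 2, 1 and 3 alternatives. With the arrays scaled to the same median 873 genes were higher and 1034 lower, and with the poly-A scaling 1040 and 766. With the floor at the 25th percentile 2244 were higher and 684 lower, and at the 60th 806 and 334. Calls at 1.5-fold gave 3210 and 1413, and at 3-fold 487 and 102.

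The excess of list medians over random lists moved by more than the SD of random lists in 15 cases and by less in 223. With the floor at the 25th percentile it was 0.76 for Hox genes, 0.08 for other homeobox genes and 1.40 for germline genes. At the 60th it was 0.03 for Hox genes, 0.17 for T-box, Gata, Fox, Sox and basic helix-loop-helix genes, -0.22 for neural markers, 0.53 for CDK inhibitors, 0.99 for germline genes and -0.26 for glycolysis genes. With a pseudocount it was 1 for germline genes and 1.34 for fibroblast markers. As the mean over probe sets it was 0.29 for H3K27 demethylases and trithorax genes, 0.04 for pluripotency factors, 0.40 for endoderm markers and -0.14 for neural markers. A higher floor measures fewer genes near background (6 Hox genes in place of 21) and a different call size counts other genes by construction. For the remaining changes the cause was not tested.

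Of the 105 named genes at least 2-fold different, 71 stayed so under all alternatives with a value and 34 fell under 2-fold in at least 1, and 51 came closer to no difference by over 1.5-fold in at least 1. Signals near the floor of 61.3 limit these results. No paired analysis was possible because each group holds 1 array, and for the same reason leaving out a replicate was not possible.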

Other observations

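The gene lists for the amino acid response and for endoplasmic reticulum (ER) chaperones were written after Nupr1, Chac1, Ddit3, Trib3 and Atf3 had been seen to be higher, but from genes whose values had not yet been looked up, and the conditions for both tests were written before those values were seen. The direction of Hspa5 was added to the ER test afterwards.

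Genes of amino acid synthesis and transport and of tRNA charging, which the transcription factor ATF4 is known to activate when amino acids are short, were higher in the Eed KO as a group. Of 35 measured, 13 were at least 2-fold higher and 1 lower, or 10 and 2 with the arrays scaled to the same median. Fibroblast markers were higher in the same array, by a median log2 ratio of 1.49, and shared 0 genes with this list. Pck2, which makes phosphoenolpyruvate in mitochondria, was 8.21-fold higher (347.1 to 2849), the cationic amino acid transporter gene Slc7a1 4.92-fold (878.9 to 4327), the transcription factor gene Atf5 3.97-fold and the branched-chain aminotransferase gene Bcat1 3.82-fold (2559 to 9786). The amino acid transporter gene Slc38a2 was lower (10776 to 4664), but at a log2 ratio of -0.83 as the mean over probe sets. These genes were named after their values were seen.

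One hypothesis is that the high Nupr1, Chac1, Ddit3, Trib3 and Atf3 signals reflect the ATF4 programme as a whole. The list's median log2 ratio of 0.71 lay at percentile 100 (rounded) of 10000 random lists, which met the condition set for it and is consistent with that hypothesis. A wider ER stress response may be present too. The ER chaperone list had a median of 0.34 at percentile 99.5, which met the condition written beforehand. Of its 19 genes 12 had a ratio above 1 and 7 below, and 1 was at least 2-fold higher, Herpud1 (4.35-fold), while fibroblast markers, with 0 shared genes, had a median of 1.49. The 7 were Pdia6, Manf, Pdia3, Hsp90b1, Xbp1, Calr and Hyou1 (-0.88 to -0.16). Hspa5, the main ER chaperone, which is not on this list, had a log2 ratio of -0.79, so the ER part was left undecided. With 1 array per group a difference in culture state between the samples, such as medium or density, cannot be separated from the loss of Eed, and it was not tested.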
